A study of Mus musculus with 19 samples.

How the data were processed

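Total RNA is the material per the labels, taken with an extraction kit after lysis in TRI Reagent. How the libraries were selected and prepared is not given in the sources used here. Gene counts were made by the authors: per the submitters' processing notes, STAR 2.5.2a and featureCounts 1.5.0-p1 were used with the mouse build mm10, and DESeq2 1.24.0 and HOMER 4.11 are named there as well. The annotation release, the strand setting of the counting and any filter on reads are not given in the sources used here. The deposited values are whole-number counts per gene for 55536 gene identifiers in each of the 19 libraries. All 55536 identifiers matched the GENCODE vM21 annotation (GRCm38), from which symbols, coordinates, GC content and transcript lengths were taken. Because the strand setting is unknown, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies or processed pseudogenes, such as those for ribosomal proteins, Rpl28, Tpt1, Hbq1b, Mndal and Zfp97, are uncertain.

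Libraries were assigned to groups by their titles and the virus named in the labels. Total counts ranged from 8385319 to 14494213 per library. All 37 pairs of replicates within a group differed by more than sampling noise (chi-square per degree of freedom between 5.335 and 41.642 over genes with at least 20 counts summed over the pair), and none of these pairs was identical. In WT, libraries 1 and 2 (6.177) and libraries 4 and 5 (5.335) formed close pairs, while pairs across these stood at 24.507 to 31.685. The tests against WT nevertheless treat the WT libraries as separate cultures of 1 kind. Genes of the mitochondrial genome took 2.33 to 3.66% of counts. Whether PCR copies were removed is not given in the sources used here.

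Genes were tested in R 4.3.3 with edgeR 4.0.16. The filterByExpr filter by group left 15335 genes. Libraries were scaled by TMM (factors 0.982 to 1.029), 1 model with the group as its only term was fitted to all 19 libraries, and the quasi-likelihood F test (robust dispersion and fit) gave each comparison, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The common biological coefficient of variation was 0.234. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM values carry a prior count of 2. The comparisons were KO minus WT, KO + HA-Zbtb20 minus KO, KO + 2KR minus KO, 2KR minus HA-Zbtb20, and each virus group minus WT. The groups, comparisons, tests, 10 alternative settings, gene lists and the naming rule were chosen before the data were examined.

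Gene lists were tested in the first 4 comparisons with limma 3.58.1 camera on voom values, with a preset correlation of 0.01 between genes of a list and adjustment over the 36 lists that had at least 3 measured genes. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way without comparing it with other genes, were run beside it. With an estimated correlation 0 lists passed in any comparison, and with fry 6 lists passed in KO against WT. In KO against WT the estimated correlation was 0.77 for the proliferation, 0.66 for the astrocyte, 0.89 for the mitochondrial and 0.31 for the ribosomal protein list. For these lists the preset 0.01 is far too low. It was 0 for the BTB paralogs and 0.01 for the chromosome 16 neighbours. The lists covered markers of hippocampal fields and of other cell types, neuronal, stress, metabolic and SUMO pathway genes, BTB paralogs, chromosome 16 neighbours and sex chromosome genes. Of 37 lists, that of blood genes had too few measured members to be tested. They were drawn from general knowledge, and fixed before the data were examined. Astrocyte, oligodendrocyte and proliferation lists shared 0 genes with another list, and the fibroblast list shared 1, Fn1, with the subicular list. Neurons and other cells of the culture may express some markers too.

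Named genes followed a rule. Zbtb20 came first, then for each of the first 4 comparisons the 10 raised and 10 lowered genes with the largest log2 fold change among those that passed, had a mean of at least 2 CPM in 1 of the groups and showed no overlap between libraries, with predicted genes and pseudogenes skipped; for the comparisons against WT it took 5 and 5. Of each list, up to 4 members with the smallest adjusted p could be named. Some genes that the rule took are not reported here. Reversal and likeness of the virus effects were measured as slopes through the origin with the 6 KO libraries split 3 and 3 over all 20 assignments, beside 20 simulations with no effect. In these and all other simulations genes vary independently, unlike real ones. Which genes likeness should cover was settled after the data were seen: all tested genes, with called genes alone beside them.

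The alternatives were DESeq2 size factors, total count scaling, no filter, a stricter filter (at least 1 CPM and 10 counts in 4 libraries), DESeq2 1.42.0, limma voom, a fit of the compared groups alone, the replicate number as a block, Xist as a covariate, and the omission of genes within 10 Mb of Zbtb20. Each library was also left out in turn. Added after the data were seen were simulations of full reversal and of no change in any group (20 each), overlaps of calls with the WT libraries split 2 and 2 or the KO libraries 3 and 3, the fibroblast list as a covariate, a smooth trend in GC content and transcript length removed by offsets (splines with 5 degrees of freedom), and the omission of WT libraries 1 and 2 or 4 and 5. Replicate numbers are shared between groups, but no label says what they stand for.

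The tests were run first on simulated data: counts drawn for the 15335 genes with 200 of them changed, 100 by 2-fold and 100 by 1.5-fold. edgeR recovered 68% and 40% of these in KO against WT, 68% and 40% in HA-Zbtb20 against KO, 68% and 35% in 2KR against KO, 65% and 34% in 2KR against HA-Zbtb20, 63% and 32% in HA-Zbtb20 against WT, and 58% and 30% in 2KR against WT. The share of false calls was 3.6%, 6.1%, 2.8%, 5.7%, 3.1% and 3.3% in that order; with DESeq2 it was between 14% and 19%. Simulated genes vary independently, unlike real ones, and recovery on the real data was not measured. A list raised by 0.5 on the log2 scale passed camera (adjusted p = 1.1e-23), and 1 unchanged list passed with it. Reversal slopes simulated at 0.5 and 0 came out at 0.46 and -0.01, and a likeness slope of 0.7 at 0.55, each as the mean of 2 assignments. The data were loaded and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Peaks or motif results, which the HOMER entry might concern, were not analysed here.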

Results

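RNA was sequenced from 19 libraries of mouse hippocampal neurons grown in primary culture. The sample labels give embryos of day 18 as the source, while the growth protocol allows newborn pups as well. Cultures received a virus after 1 day and were lysed after 5 days. Zbtb20 is a BTB zinc finger transcription factor with a known role in the formation of hippocampal fields. The title of the series concerns its SUMOylation, the attachment of the small protein SUMO, and its function in neural development. Wild-type cultures with a virus coding for eGFP (WT, n = 4) served as the reference for Zbtb20 knockout cultures with the same virus (KO, n = 6). Knockout cultures also received HA-tagged Zbtb20 (KO + HA-Zbtb20, n = 5) or a form of it that the labels call 2KR (KO + 2KR, n = 4). The labels do not describe the change that 2KR stands for. Total counts per library were 9171891 to 9974395 in WT, 8617761 to 14366134 in KO, 8385319 to 11416739 in KO + HA-Zbtb20 and 12718889 to 14494213 in KO + 2KR. That replicates are separate cultures rests on the replicate numbers in the labels, which do not say what a number stands for. Each group held female and male libraries, and those of unlike sex within a group cannot come from the same animal. The p-values measure the spread between these libraries, part of which may be technical.

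Zbtb20 (ENSMUSG00000022708, chromosome 16, 42875881 to 43642602, plus strand, GRCm38) was counted in every library. In WT the 4 libraries, numbered 1, 2, 4 and 5 in the labels, held 336, 421, 692 and 453 CPM, a mean of 475 ± 152 (SD, n = 4). The KO libraries held 280, 209, 134, 115, 173 and 168 CPM, a mean of 180 ± 59.2 (SD, n = 6). None of them reached the lowest WT library. Zbtb20 fell by 1.40 ± 0.25 (SE) on the log2 scale in KO against WT, with an adjusted p of 0.0048 from edgeR. It passed without any single library and without WT libraries 1 and 2 (-1.67). Without WT libraries 4 and 5, which leaves 2 WT libraries, it stood at -1.08 and missed the threshold. KO + HA-Zbtb20 held 340, 380, 362, 233 and 208 CPM (mean 304 ± 78.7, SD, n = 5) and KO + 2KR held 367, 290, 231 and 215 CPM (mean 276 ± 69.2, SD, n = 4). Against KO, the log2 fold change was 0.76 ± 0.24 (adjusted p = 0.15) with HA-Zbtb20 and 0.62 ± 0.25 (adjusted p = 0.19) with 2KR, so neither passed the test. Against WT it was -0.64 ± 0.26 (adjusted p = 0.14) and -0.79 ± 0.28 (adjusted p = 0.083). The direct difference between 2KR and HA-Zbtb20 was -0.14 ± 0.26, with a 95% interval from -0.70 to 0.42. A count per gene cannot tell reads of the deleted gene's remaining exons, or of the virus coding sequence, from those of the intact transcript, so these values check the labels only in part.

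**Figure D1:**
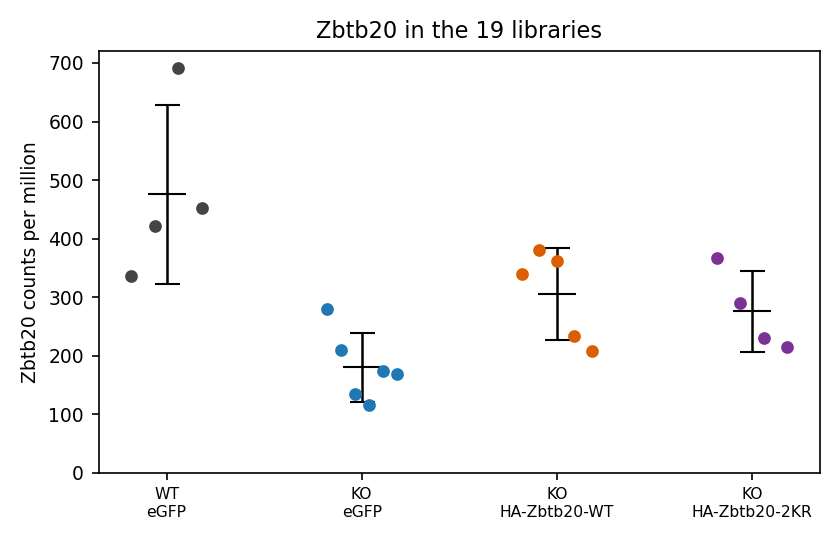
Zbtb20 in CPM (vertical axis) in each of the 19 libraries by group (horizontal axis), with the mean and SD of each group. All 6 KO libraries lie at or below 280 CPM and all 4 WT libraries at or above 336 CPM, with the libraries of both HA-tagged forms between 208 and 380 CPM.

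The libraries of one group were not alike in all respects. On the first principal component of the tested genes, which held 27.9% of the variance, the KO libraries ranged from -39.9 to 44.4 and the KO + 2KR libraries from -49.1 to 16.5. On the second, which held 17% of the variance, WT libraries 1 and 2 lay at 57.2 and 53.5, and WT libraries 4 and 5 at 22.5 and 18.5. The mean log2 CPM of 14 astrocyte markers was 8.43 in both WT 1 and WT 2, against 7.08 in WT 4 and 7.38 in WT 5, and between 6.01 and 7.84 in the other libraries. The mean log2 CPM of 12 fibroblast and meningeal markers ranged from 1.89 in KO + HA-Zbtb20 library 1 to 6.29 in KO + 2KR library 3. Its most abundant members in KO were Igfbp2 at 265 ± 309 CPM, Fn1 at 219 ± 237 CPM and Col3a1 at 129 ± 148 CPM (SD, n = 6). By Xist and the Y-linked gene Ddx3y, WT held 1 female and 3 male libraries and KO 4 female and 2 male. KO + HA-Zbtb20 held 3 female and 2 male libraries, and KO + 2KR 1 female and 3 male.

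**Figure D2:**
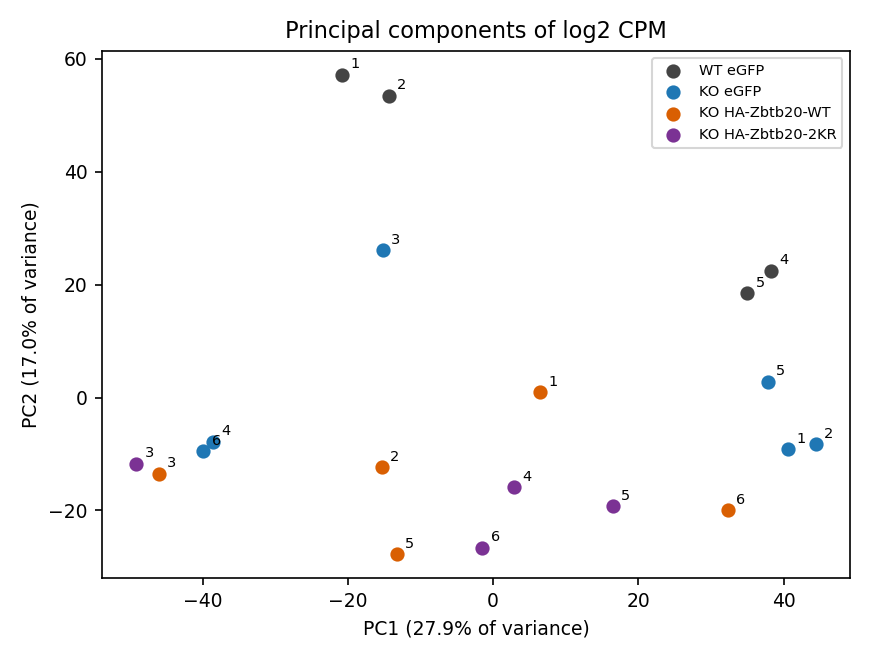
First principal component (horizontal axis, 27.9% of the variance) against the second (vertical axis, 17% of the variance) of log2 CPM over the tested genes; each point is a library, coloured by group and numbered by replicate. WT libraries 1 and 2 lie above 50 on the second component, and WT libraries 4 and 5 at 22.5 and 18.5.

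Loss of Zbtb20 was addressed by comparing KO with WT cultures, both with the eGFP virus. Gna14, which codes for a G protein alpha subunit of the Gq class, rose from 0.188 ± 0.182 CPM in WT (SD, n = 4) to 6.71 ± 1.68 CPM in KO (SD, n = 6). The anion transporter gene Slc26a7 rose from 5.28 ± 1.61 to 29.4 ± 12.1 CPM. Tfap2c, coding for the transcription factor AP-2 gamma, rose from 2.2 ± 0.608 to 10.8 ± 3.77 CPM and the HMG-box gene Tox from 14.1 ± 4.9 to 39.4 ± 12.1 CPM. Pcdh20, which codes for a protocadherin, fell from 80.2 ± 18.6 CPM in WT to 14.2 ± 5.64 CPM in KO. Pdyn, the precursor of dynorphin peptides, fell from 19.4 ± 5.95 to 3.79 ± 1.09 CPM. Tacr3, the neurokinin 3 receptor, fell from 24 ± 0.75 to 4.96 ± 1.97 CPM and Chrm1, the M1 muscarinic receptor, from 42.8 ± 10.6 to 11.6 ± 3.83 CPM.

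The log2 fold change of Gna14 (chromosome 19, 16435762 to 16610820) was 5.09 ± 0.40 (SE) with an adjusted p of 1.8e-06 from edgeR. For Slc26a7 (chromosome 4, 14502430 to 14621805) it was 2.47 ± 0.29 (adjusted p = 0.00011). Tfap2c (chromosome 2, 172549593 to 172558622) rose by 2.30 ± 0.29 (adjusted p = 0.00019) and Tox (chromosome 4, 6686353 to 6991557) by 1.48 ± 0.24 (adjusted p = 0.002). For Pcdh20 (chromosome 14, 88464743 to 88471396) it was -2.50 ± 0.26 (adjusted p = 4.2e-05) and for Chrm1 (chromosome 19, 8663789 to 8683587) -1.88 ± 0.22 (adjusted p = 7.5e-05). Tacr3 (chromosome 3, 134829007 to 134934579) fell by 2.27 ± 0.28 (adjusted p = 0.00014) and Pdyn (chromosome 2, 129686565 to 129699844) by 2.35 ± 0.29 (adjusted p = 0.00018). Other raised genes that the naming rule took were the Hedgehog effector Gli1 (3.0 ± 0.71), the thyrotropin-releasing hormone receptor gene Trhr (2.03 ± 0.40), the meiotic cohesin gene Rec8 (1.89 ± 0.31), Hbq1b (1.67 ± 0.29) and the kinetochore gene Ska1 (1.5 ± 0.38), with adjusted p from 0.0026 to 0.042. The other lowered ones were Sox10 (-3.34 ± 0.72), a regulator of the oligodendrocyte lineage, the astrocyte genes S100b (-2.94 ± 0.47) and Aqp4 (-2.82 ± 0.59), Map3k19 (-2.52 ± 0.49), Tbata (-2.40 ± 0.41) and Mndal (-1.92 ± 0.49), with adjusted p from 0.0017 to 0.041. Hbq1b and Mndal belong to families of similar copies, and their counts are uncertain for that reason.

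In all, 375 of 15335 tested genes passed an adjusted p of 0.05 in edgeR, 200 higher and 175 lower in KO, and 2230 had an unadjusted p under 0.05. The balance of directions depended on the setting. It was 390 higher and 323 lower in DESeq2, 119 and 173 in limma voom, and 189 and 297 without WT libraries 4 and 5. The libraries of the 2 groups did not overlap for 290 of the 375, which were picked for their difference. Over all tested genes they did not overlap for 611 (3.98%), where chance gives 0.952% on average over all groupings of these libraries. Genes vary together, so a single grouping can lie far from that average. Of the 20 genes that the naming rule took, 14 passed the test whichever library was left out, and 10 did so under every other setting as well: Gna14, Slc26a7, Tfap2c, Rec8, Hbq1b, Tox, Pcdh20, Pdyn, Tacr3 and Chrm1. Ska1 no longer passed in 8 of the 10 fits without 1 library, Mndal in 6 and Gli1 in 4. Without WT libraries 1 and 2, which leaves 2 WT libraries, 225 genes passed and 13 of the 20 did. Those that did not were Ska1 (log2 fold change 1.33 in this fit), Sox10 (-2.38), S100b (-1.83), Aqp4 (-2.27), Map3k19 (-2.34), Tbata (-2.08) and Mndal (-1.30). Without WT libraries 4 and 5, 16 of the 20 did, and Gli1 (2.01), Trhr (1.43) and Ska1 (1.67) were among those that did not. Of the genes tested within 10 Mb of Zbtb20, 2 of 90 passed, Zbtb20 itself not counted, against 372 of 15244 elsewhere (Fisher's exact test, two-sided, p = 1).

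**Figure D3:**
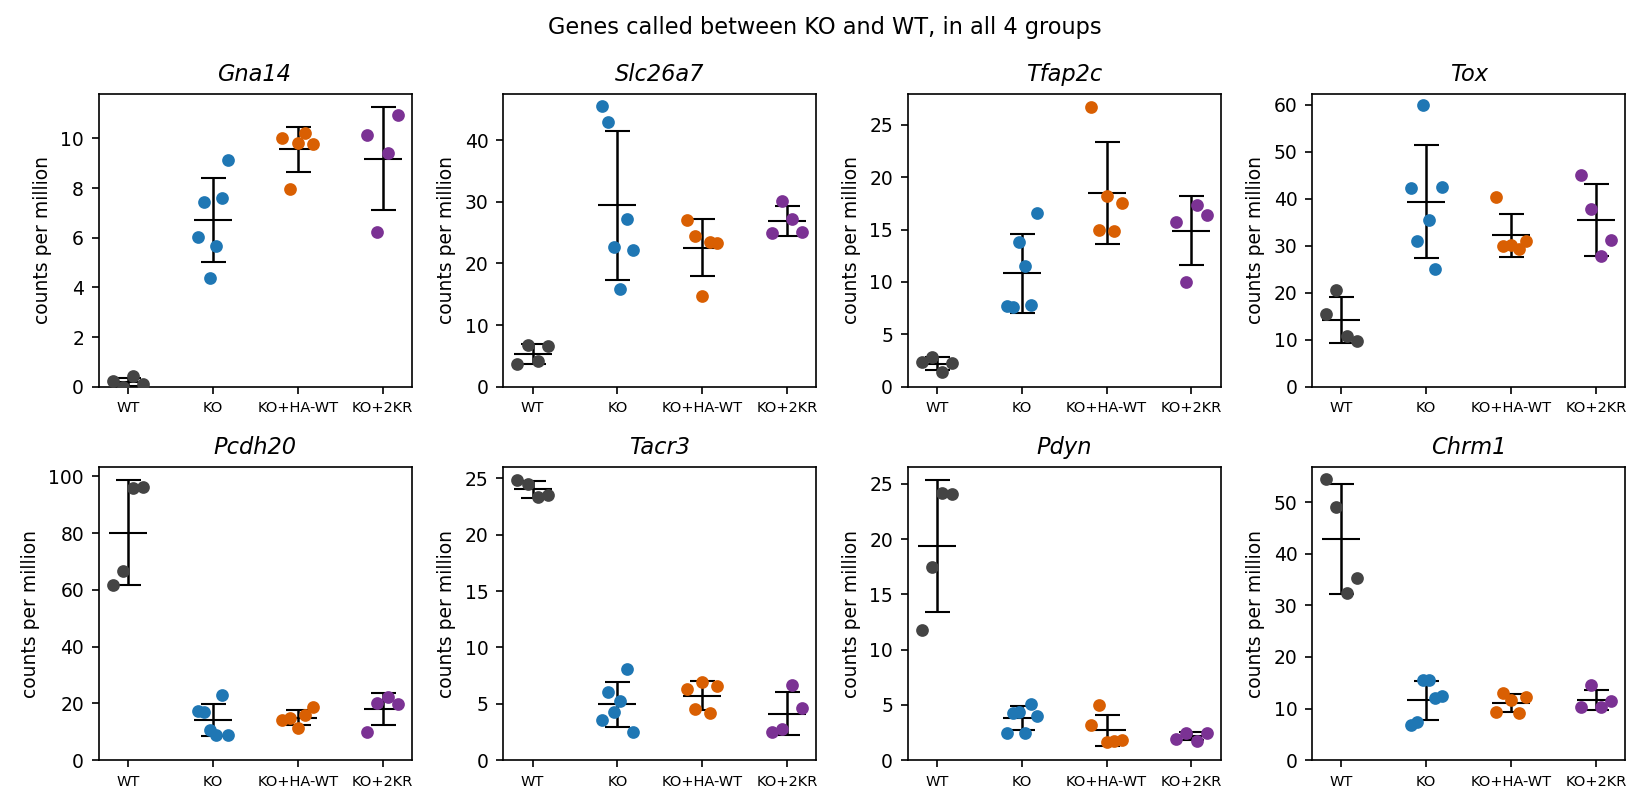
CPM (vertical axes) of Gna14, Slc26a7, Tfap2c, Tox, Pcdh20, Tacr3, Pdyn and Chrm1 in each library by group (horizontal axes), with the mean and SD of each group. The KO libraries do not overlap the WT libraries for any of the 8 genes.

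Genes of the cell cycle rose in KO. All 20 measured members of the proliferation list lay higher in KO than in WT, with a median log2 fold change of 0.80. Of these, 8 passed over all genes and 20 when adjusted over the list alone. Birc5, an inhibitor of apoptosis with a mitotic role, rose by 1.22 ± 0.20 (SE, adjusted p = 0.0025), the cyclin-dependent kinase Cdk1 by 1.12 ± 0.23 (adjusted p = 0.013) and the checkpoint kinase Bub1 by 1.02 ± 0.23 (adjusted p = 0.02). The replication licensing gene Mcm3 rose by 0.97 ± 0.21 (adjusted p = 0.018). The list passed limma's camera test, which sets a list against all other genes, with the preset correlation of 0.01 (adjusted p = 1.1e-17). With the estimated correlation of 0.77 between its genes it did not pass camera (adjusted p = 0.23). Without WT libraries 1 and 2 the median was 0.59 and 0 of the 20 members passed over all genes in edgeR, with Birc5 at 1.03 and Cdk1 at 0.98.

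Markers of glia stood lower in KO. Of 14 astrocyte markers, 0 rose and 3 fell: S100b, Aqp4 and the glutamate transporter gene Slc1a2 (-0.82 ± 0.15, adjusted p = 0.0058). Adjusted over the list alone, 0 rose and 4 fell, and the median was -0.72 (camera, adjusted p = 6.1e-06; adjusted p = 0.39 with an estimated correlation). Of 12 oligodendrocyte lineage markers, 0 rose and 2 fell, Sox10 and Olig2 (-1.36 ± 0.34, adjusted p = 0.037); Olig2 no longer passed in 8 of the 10 fits that left out 1 library. Adjusted over the list alone, 0 rose and 7 fell, with a median of -1.01 (adjusted p = 1.1e-05; adjusted p = 0.23 with an estimated correlation). In both lists WT libraries 1 and 2 stood highest. Without them the medians were 0.02 for astrocyte and -0.39 for oligodendrocyte lineage markers, and 0 members of either list passed in edgeR. In that fit Slc1a2 stood at -0.60 and Olig2 at -0.98. The 10 measured microglia markers had a median of -0.53 with 0 members past the test (adjusted p = 0.079), and 8 endothelial and mural markers one of 0.53, also with 0 (adjusted p = 0.39). The 12 fibroblast and meningeal markers had a median of 1.39 and 0 members past the test over all genes, with 1, the proteoglycan gene Dcn (1.52 ± 0.40), adjusted over the list alone (camera, adjusted p = 0.057). Their median was 2.55 without WT libraries 1 and 2, with 1 member past the test over all genes, and 1.06 without 4 and 5, with 0. The 8 choroid plexus and ependymal markers had a median of 0.42 with 0 members past the test (adjusted p = 0.94), and the 13 neural progenitor markers one of 0.34, again with 0 (adjusted p = 0.21).

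**Figure D4:**
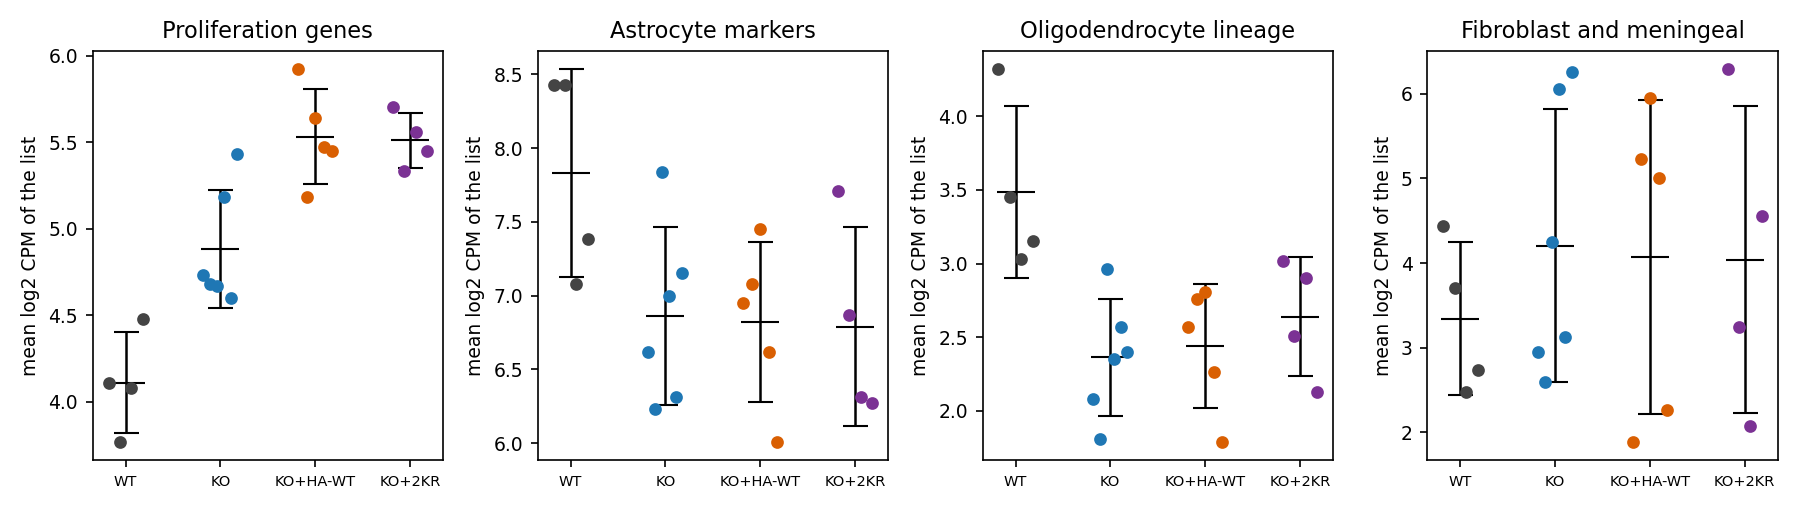
Mean log2 CPM (vertical axes) of the proliferation, astrocyte, oligodendrocyte lineage and fibroblast lists in each library by group (horizontal axes), with the mean and SD of each group. WT libraries 1 and 2 hold the highest astrocyte values, 8.43 in each, and the proliferation values are 3.77 to 4.48 in WT, 4.6 to 5.43 in KO, 5.18 to 5.92 in KO + HA-Zbtb20 and 5.33 to 5.7 in KO + 2KR.

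Genes that mark hippocampal fields or neuron types moved in part. Of 8 CA3 pyramidal markers, 1 fell, the kainate receptor gene Grik4 (-1.31 ± 0.21, adjusted p = 0.0016), and 4 fell when adjusted over the list alone. The median was -0.49 (camera, adjusted p = 0.011; adjusted p = 0.23 with an estimated correlation). Of 9 dentate granule markers, 2 fell, Dock10 (-1.29 ± 0.27, adjusted p = 0.014) and the semaphorin gene Sema5a (-1.28 ± 0.29, adjusted p = 0.024), and adjusted over the list alone 3 fell and 1 rose. The median was -0.52 (adjusted p = 0.022; adjusted p = 0.23 with an estimated correlation). The 17 interneuron markers had a median of -0.43 with 16 of them lower in KO and 0 past the test singly, also adjusted over the list alone (adjusted p = 2.7e-05; adjusted p = 0.39 with an estimated correlation). Among 8 CA1 pyramidal markers 0 passed, and 2 rose adjusted over the list alone, Ccn3 (0.57 ± 0.18) among them. The list's median of -0.09 and its mean of 0.21 differed in sign, and camera pointed up (adjusted p = 0.83). Among 5 subicular and retrosplenial markers 1 fell, the transcription factor gene Etv1 (-1.45 ± 0.25, adjusted p = 0.0034), while 2 rose and 1 fell adjusted over the list alone. Their median was 0.94 (adjusted p = 0.84, up), and limma's fry pointed down. Of 8 Cajal-Retzius markers 1 fell, also adjusted over the list alone, the calretinin gene Calb2 (-1.84 ± 0.40, adjusted p = 0.02), with a median of 0.03, a mean of -0.01 and an adjusted p of 0.92. Of 13 isocortical genes held to be repressed by Zbtb20, 1 rose, the cofactor gene Zfpm2 (0.80 ± 0.17, adjusted p = 0.016), and 2 fell, Etv1 and Bhlhe22 (-0.47 ± 0.09, adjusted p = 0.0056). Adjusted over the list alone, 4 rose and 4 fell, and the median was -0.18 (adjusted p = 0.38). Grik4, Etv1 and Bhlhe22 passed in every fit run. Dock10, Calb2 and Zfpm2 and the CA3 list no longer passed without WT libraries 1 and 2, and Sema5a, Calb2 and the dentate list without 4 and 5. The dentate list did not pass without any single WT library or without KO 4, and the CA3 list not without WT 1. In these fits of fewer libraries the log2 fold change of Calb2 was -2.04 and -1.61, that of Dock10 -0.94, of Zfpm2 0.44 and of Sema5a -1.01.

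Some genes for peptides, guidance receptors and synaptic proteins fell, and fewer rose. Of 21 neuropeptide and growth factor genes, 0 rose and 3 fell, also adjusted over the list alone: Pdyn, Fgf1 (-2.06 ± 0.36, adjusted p = 0.0044) and Fgf14 (-0.46 ± 0.12, adjusted p = 0.045), with a median of -0.39 (camera, adjusted p = 0.00031; adjusted p = 0.23 with an estimated correlation). Among 40 axon guidance and adhesion genes, 3 rose and 5 fell, or 5 and 12 adjusted over the list alone, with a median of -0.09 (adjusted p = 0.057 in camera, while fry passed the list). The ephrin receptor gene Epha7 fell by 1.11 ± 0.10 (adjusted p = 5e-06), the semaphorin receptor gene Nrp2 by 0.86 ± 0.10 (adjusted p = 6.6e-05), Epha4 by 0.89 ± 0.12 (adjusted p = 0.00054) and Sema3c by 1.46 ± 0.27 (adjusted p = 0.0064). Of 32 glutamate receptor and postsynaptic genes 1 fell, the calcium/calmodulin-dependent kinase gene Camk2a (-0.86 ± 0.12, adjusted p = 0.00054), with 2 higher and 2 lower adjusted over the list alone (median -0.13, adjusted p = 0.057). Of 29 presynaptic genes 2 fell, Cplx2 (-0.67 ± 0.10, adjusted p = 0.0014) and the vesicular glutamate transporter gene Slc17a6 (-1.23 ± 0.21, adjusted p = 0.0031), with 1 higher and 5 lower adjusted over the list alone (median -0.08, adjusted p = 0.057). Of 17 GABA-A receptor and inhibitory synapse genes 1 rose, Slc12a2 (0.50 ± 0.13, adjusted p = 0.043), and 1 fell, Gabra5 (-0.50 ± 0.11, adjusted p = 0.018), with 1 and 2 adjusted over the list alone (median -0.05, adjusted p = 0.38). Of 28 voltage-gated channel genes 1 fell, also adjusted over the list alone, the potassium channel gene Kcnd2 (-0.68 ± 0.12, adjusted p = 0.0035; list median -0.06, adjusted p = 0.06). The 21 neurite and cytoskeleton genes had 0 members past the test (median -0.12, adjusted p = 0.22). Epha7, Nrp2, Epha4, Camk2a, Cplx2 and Kcnd2 passed in every fit run. Fgf1, Fgf14 and Slc12a2 no longer passed without WT libraries 1 and 2, and Fgf14, Sema3c, Slc17a6, Gabra5, Slc12a2 and the peptide list without 4 and 5. Fgf14 and Slc12a2 also no longer passed in 8 of 10 fits that left out 1 library. The fold changes of Fgf14 (-0.54 and -0.38) and Slc12a2 (0.57 and 0.42) kept their direction there, as did those of Fgf1 (-1.67), Sema3c (-0.82), Slc17a6 (-0.96) and Gabra5 (-0.40).

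Stress, metabolic and housekeeping lists showed few single changes. Of 15 immediate early genes 1 rose, Fosl2 (1.10 ± 0.25, adjusted p = 0.027), and 1 fell, Egr3 (-1.01 ± 0.22, adjusted p = 0.019), the same numbers as adjusted over the list alone (median -0.07, adjusted p = 0.92). Of 15 p53 target genes 1 rose, also adjusted over the list alone, Plk2 (0.51 ± 0.10, adjusted p = 0.0058; list median 0.09, adjusted p = 0.11). The hypoxia and glycolysis list, 18 gene identifiers for 17 symbols because Aldoa has 2, had a median of -0.29 and passed camera (adjusted p = 0.0032; adjusted p = 0.68 with an estimated correlation), with 0 members past the test singly or adjusted over the list alone. Its mean log2 CPM was 6.44 in WT library 1 and 5.32 to 5.48 in the other WT libraries. No member passed, and the list itself did not pass camera, for 14 integrated stress response genes (median -0.03, mean 0.04, adjusted p = 0.82, down), 13 unfolded protein and heat shock genes (median -0.01, mean -0.06, adjusted p = 0.93, up) and 18 interferon response genes (median 0.47, adjusted p = 0.46). The same held for 18 cholesterol synthesis genes (median -0.04, adjusted p = 0.75), 18 SUMO pathway genes (median 0.04, adjusted p = 0.34), 35 ribosomal protein genes (median 0.06, adjusted p = 0.15), 25 nuclear genes of oxidative phosphorylation (median -0.06, adjusted p = 0.057) and 7 genes of the mitochondrial genome (median -0.10, adjusted p = 0.057). Among 12 BTB zinc finger paralogs of Zbtb20, 0 passed over all genes and 1 fell adjusted over the list alone, Zbtb18 (-0.36 ± 0.11; list median -0.09, adjusted p = 0.079). Of 24 neighbours of Zbtb20 on chromosome 16, 2 fell, Gramd1c (-1.11 ± 0.24, adjusted p = 0.015) and Slc35a5 (-0.35 ± 0.09, adjusted p = 0.045), with 4 lower adjusted over the list alone (median -0.12, adjusted p = 0.079). The 5 sex chromosome genes had a median of -1.21 with 0 past the test (adjusted p = 0.43), in libraries with unequal shares of the sexes. Fosl2, Egr3, Plk2, Gramd1c, Slc35a5 and the hypoxia and glycolysis list no longer passed without WT libraries 1 and 2, where the genes stood at 0.76, -0.83, 0.52, -1.10 and -0.26 in that order. Without WT libraries 4 and 5, Plk2 (0.49) and Gramd1c (-1.14) did not pass either. The list did not pass without WT 1 alone, and Slc35a5 not in 8 and Fosl2 not in 4 of 10 fits that left out 1 library.

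Re-expression was addressed by comparing KO + HA-Zbtb20 with KO. Ncapg, a condensin subunit, rose from 11.9 ± 2.85 CPM in KO (SD, n = 6) to 24.4 ± 5.44 CPM (SD, n = 5), and Smc4, the condensin ATPase, from 49.2 ± 7.11 to 92.5 ± 20.2 CPM. The log2 fold change was 1.03 ± 0.16 (SE, adjusted p = 0.018) for Ncapg (chromosome 5, 45669919 to 45700546) and 0.91 ± 0.13 (adjusted p = 0.016) for Smc4 (chromosome 3, 69004738 to 69034623). The other raised genes taken by the naming rule were Ect2 (0.98 ± 0.19), the spindle motor gene Kif11 (0.95 ± 0.17), Hells (0.93 ± 0.18), Gas2l3 (0.92 ± 0.17), Ncaph (0.84 ± 0.17), the kinetochore motor gene Cenpe (0.83 ± 0.14), the cyclin gene Ccne2 (0.81 ± 0.15) and Tbc1d31 (0.75 ± 0.13), with adjusted p from 0.04 to 0.047. The 4 genes that fell were Cox10 (-0.48 ± 0.09), Ankrd13d (-0.46 ± 0.09), Slc25a28 (-0.36 ± 0.07) and Gtpbp2 (-0.35 ± 0.07), each with an adjusted p of 0.047.

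Of 15335 genes, 30 passed in edgeR, 26 higher and 4 lower with HA-Zbtb20. In all, 2280 had an unadjusted p under 0.05, and 28 of the 30 showed no overlap between libraries. Over all tested genes 251 (1.64%) showed none, where chance gives 0.433% on average over all groupings. Since genes vary together, this share does not exclude chance. The count of called genes fell to 0 in edgeR when only these 2 groups were fitted and when a trend with GC content and transcript length was removed, with 1909 and 1284 genes at an unadjusted p under 0.05. With the replicate number as a block it was also 0 in edgeR, with 2176 such genes, and with Xist as a covariate it was 5. In the fit of all libraries, DESeq2 called 409 genes, 242 higher and 167 lower, and limma voom 59, 53 higher and 6 lower. Without KO library 1, edgeR called 82 higher and 75 lower. Of the 14 named genes, 0 passed in every fit that left out 1 library.

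Among the fixed lists, all 20 proliferation genes lay higher with HA-Zbtb20 (median 0.57). Of these, 1 passed over all genes and 19 adjusted over the list alone (camera, adjusted p = 7.3e-20; adjusted p = 0.69 with an estimated correlation). The neural progenitor list lay higher (median 0.40, 0 members past the test; adjusted p = 0.0041, and 0.76 as adjusted p with an estimated correlation). HA-Zbtb20 library 1 scored 5.73 on it and the other 4 libraries 4.77 to 4.97. Without library 1 the median was 0.24 and the list did not pass. The 7 genes of the mitochondrial genome lay higher (median 0.26; 0 over all genes, 6 adjusted over the list alone; adjusted p = 2.3e-05; adjusted p = 0.76 with an estimated correlation). The 35 ribosomal protein genes lay lower (median -0.20; 0 over all genes, 4 adjusted over the list alone; adjusted p = 1.3e-06; adjusted p = 0.76 with an estimated correlation), and many of them have processed pseudogenes that can share reads. With the trend in GC content and length removed, the median was 0.12 for the mitochondrial and -0.13 for the ribosomal list. Camera also passed the oxidative phosphorylation list (median -0.06, adjusted p = 0.0091), the hypoxia and glycolysis list (median -0.24, adjusted p = 0.018) and the microglia list (median -0.55, adjusted p = 0.01), each with 0 members past the test, and adjusted p = 0.97, 0.97 and 0.76 with an estimated correlation. Without HA-Zbtb20 library 1 these 3 lists did not pass either. The same held for the oxidative phosphorylation list without KO 4 or KO 5, the hypoxia and glycolysis list without KO 3 and the microglia list without HA-Zbtb20 6. The SUMO pathway list had a median of 0.05 and 0 members past the test. Median, mean and test differed in sign for 5 lists that did not pass (subicular, astrocyte, unfolded protein, BTB paralogs and sex chromosome).

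The 2KR form was compared with KO in the same way. Bub1 rose from 13 ± 4.1 CPM in KO (SD, n = 6) to 28.3 ± 3.23 CPM (SD, n = 4), the mitotic cyclin gene Ccnb1 from 8.77 ± 3.17 to 18.6 ± 2.07 CPM, and Smc4 from 49.2 ± 7.11 to 95.5 ± 11.6 CPM. Their log2 fold changes were 1.12 ± 0.21 (SE, adjusted p = 0.032), 1.08 ± 0.22 (adjusted p = 0.033) and 0.96 ± 0.14 (adjusted p = 0.016). Raised genes also included the zinc finger gene Zfp97 (1.42 ± 0.31), Adgrv1 (1.09 ± 0.26), Gas2l3 (1.05 ± 0.18), Ncapg (1.04 ± 0.17), the DNA glycosylase gene Neil3 (1.03 ± 0.24), Ect2 (0.96 ± 0.20) and the cohesin acetyltransferase gene Esco2 (0.94 ± 0.22), with adjusted p from 0.02 to 0.045. Selenow, which codes for a selenoprotein, fell from 604 ± 89 to 405 ± 42.8 CPM (log2 fold change -0.58 ± 0.12, adjusted p = 0.033). The other lowered genes were Fxyd2 (-1.29 ± 0.31), Rpl28 (-1.02 ± 0.19), Disp3 (-0.89 ± 0.22), Akr7a5 (-0.67 ± 0.14), Tpt1 (-0.64 ± 0.16), Zfp414 (-0.64 ± 0.14), Pusl1 (-0.58 ± 0.13), Matk (-0.56 ± 0.12) and the T-type calcium channel gene Cacna1h (-0.56 ± 0.12), with adjusted p from 0.033 to 0.045. Rpl28 and Tpt1 have processed pseudogenes and Zfp97 has close paralogs, so their counts are uncertain.

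In edgeR 208 genes passed, 110 higher and 98 lower with 2KR. The balance of directions depended on the setting: 368 higher and 722 lower in DESeq2, 223 and 222 in limma voom, and 47 and 14 with no filter, while with DESeq2 size factors in edgeR more genes fell (127 of 229) than rose. In all, 2821 had an unadjusted p under 0.05, and 183 of the 208 showed no overlap. Over all tested genes 728 (4.75%) showed none, where chance gives 0.952% on average over all groupings. Since genes vary together, this share does not exclude chance either. The count of called genes fell to 0 in edgeR when only these 2 groups were fitted, when the trend with GC content and length was removed and with Xist as a covariate, with 2459, 1259 and 2430 genes at an unadjusted p under 0.05. With the replicate number as a block it was also 0 in edgeR, with 2837 such genes. In the fit of all libraries, DESeq2 called 1090 genes in total and limma voom 445. Of the 20 named genes, 0 passed in every fit that left out 1 library. Genes called higher had a median GC content of 40.9% and those called lower 57.4%, against 49.3% for all tested genes. All 20 proliferation genes lay higher with 2KR (median 0.53). Of these, 3 passed over all genes and 13 adjusted over the list alone (camera, adjusted p = 1.2e-13; adjusted p = 0.83 with an estimated correlation). The 7 mitochondrial genes lay higher (median 0.33; 0 over all genes, 7 adjusted over the list alone; adjusted p = 3e-05; adjusted p = 0.88 with an estimated correlation) and the 35 ribosomal protein genes lower (median -0.34; 3 over all genes, 14 adjusted over the list alone; adjusted p = 1.5e-09; adjusted p = 0.83 with an estimated correlation). With the trend removed, these medians were 0.10 and -0.23. The hypoxia and glycolysis list had a median of -0.31 and 0 members past the test (adjusted p = 0.038; adjusted p = 0.92 with an estimated correlation), and did not pass in 5 of 10 fits that left out 1 library (KO 2, 3 or 5 or 2KR 3 or 5). The SUMO pathway list had a median of 0.08, also with 0. Median, mean and test differed in sign for 6 lists that did not pass (CA3, subicular, endothelial, fibroblast, choroid plexus and axon guidance).

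Whether either form moved the genes changed in KO back toward WT was asked of the 375 genes called in KO against WT. Zbtb20 itself stood 0.76 and 0.62 above KO on the log2 scale without passing the test (edgeR, adjusted p = 0.15 and 0.19). Weak re-expression is thus not told apart from a lack of reversal. With HA-Zbtb20, 186 of the 375 (49.6%) moved opposite to the knockout change, and with 2KR 179 (47.7%). Both changes use the same KO libraries, which by itself pushes genes to opposite signs. With the KO libraries split 3 and 3, these shares had medians of 47.08% (22.3 to 67) and 39.09% (23.52 to 54.41) over 20 assignments. Adjusted over the 375 alone, 13 genes moved back and 42 moved further with HA-Zbtb20, and 10 moved back and 29 further with 2KR. Over all genes, 0 moved back and 7 further with HA-Zbtb20 (edgeR; 2280 of all tested genes had an unadjusted p under 0.05, and over all tested genes DESeq2 called 409 and limma voom 59), and 4 back and 16 further with 2KR. Against WT, 299 of the 375 (79.7%) still passed in the same direction with HA-Zbtb20 and 303 (80.8%) with 2KR. The 375 were chosen by their difference from the same WT libraries. In groups simulated with no effect of the virus, a median of 981 genes was called in KO and 58.6% and 51.1% of them still passed. With full reversal simulated it was 0% and 0% of a median of 1010. These called sets are larger than the 375, so the shares are not matched. Gna14 stood at 9.55 ± 0.907 CPM with HA-Zbtb20 (SD, n = 5) and 9.19 ± 2.06 CPM with 2KR (SD, n = 4), Tfap2c at 18.5 ± 4.85 CPM with HA-Zbtb20, and Pdyn at 2.69 ± 1.42 and 2.16 ± 0.378 CPM, none of them between the KO and WT means. Means between those of KO and WT were seen for Slc26a7 (22.6 ± 4.68 and 26.9 ± 2.42 CPM), Tox (32.2 ± 4.57 and 35.5 ± 7.6 CPM) and Rec8 (2.51 ± 0.454 and 3.83 ± 1.14 CPM). Of the 20 genes named for KO, 10 had such a mean with HA-Zbtb20 and 10 with 2KR. With the 6 KO libraries split 3 and 3 so that no library served both fold changes, the slope of the change with virus on the knockout change, its sign turned so that 1 would be full reversal, had a median of -0.04 over 20 assignments (-0.51 to 0.15) with HA-Zbtb20 and -0.07 (-0.51 to 0.10) with 2KR. Without the split the slopes were -0.02 and -0.04, and groups simulated with no effect gave 0.10 and 0.11.

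**Figure D5:**
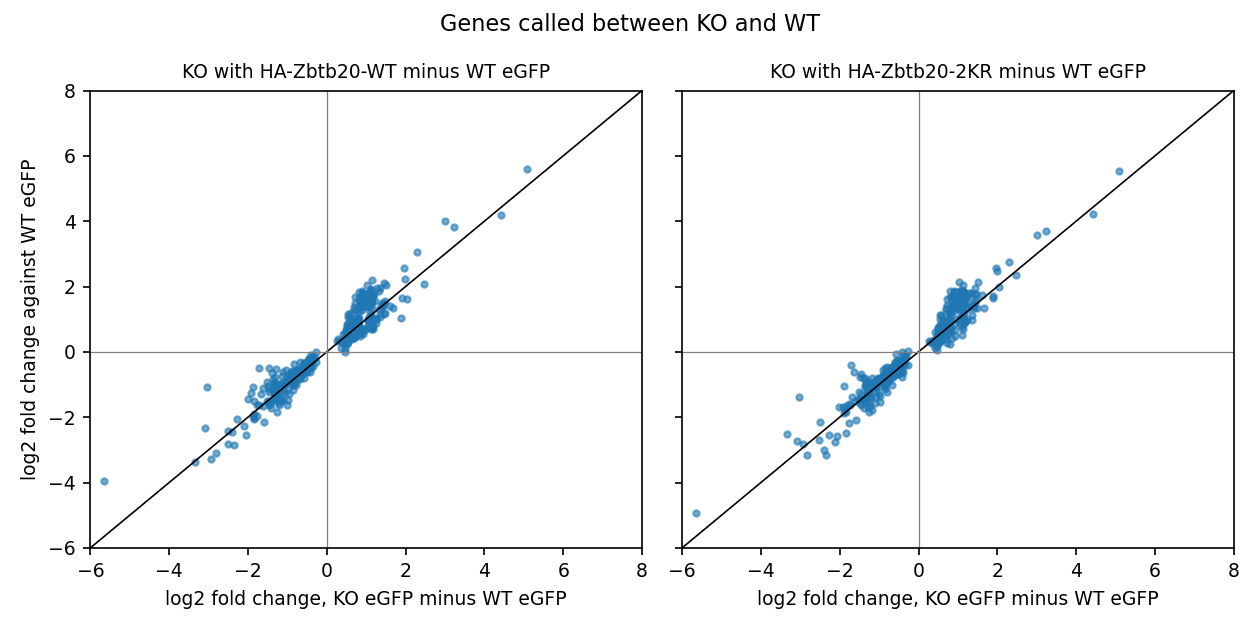
Log2 fold change against WT of KO + HA-Zbtb20 and of KO + 2KR (vertical axes) against the log2 fold change of KO against WT (horizontal axes) for the 375 genes called in KO; the diagonal marks equal change. The genes were chosen by their difference from the same WT libraries, and 100% keep the sign of the knockout change with HA-Zbtb20 and 99.5% with 2KR. Simulated full reversal keeps 72.4% and 71.8%, and no effect of the virus 99.9% and 99.8%, of larger called sets that are not matched to the 375. Partial reversal, which could keep the sign as well, was not simulated for these shares.

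The direct test between 2KR and HA-Zbtb20 asked whether the forms differed. The difference was 0.05 ± 0.14 (SE, 95% interval -0.26 to 0.35) for Smc4 and 0.10 ± 0.22 (-0.36 to 0.56) for Bub1. For genes changed in KO it was -0.06 ± 0.26 (-0.61 to 0.50) for Gna14, 0.27 ± 0.28 (-0.32 to 0.86) for Pcdh20 and -0.32 ± 0.33 (-1.02 to 0.39) for Pdyn. Of 51 named genes, 48 had an interval that held 0 and 37 an interval within 1 log2 unit of 0 on either side; the 3 that did not hold 0 were Rpl28 (-0.46, -0.88 to -0.03), Tpt1 (-0.36, -0.70 to -0.02) and Cacna1h (-0.25), unadjusted for the number of genes. No gene passed in edgeR (0 of 15335, with 157 at an unadjusted p under 0.05), in DESeq2 (0, with 173) or in limma voom (0, with 200). The groups did not overlap for 105 genes (0.68%), where chance gives 1.59% on average over all groupings. Over all tested genes the 95% interval extended by a median of 0.35 to either side of the estimate, and by less than 1 for 87.7% of genes. Differences smaller than these widths are not excluded.

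Of the fixed lists, camera passed 7 between the forms, none with a single member past the test over all genes or adjusted over the list alone. Microglia (median 0.15, adjusted p = 0.0066), GABA-A receptor (0.10, 0.044), integrated stress response (0.10, 0.044) and unfolded protein genes (0.10, 0.0068) lay higher with 2KR. Cajal-Retzius (-0.60, adjusted p = 0.0026), neurite (-0.07, 0.0066) and ribosomal protein genes (-0.09, 0.0026) lay lower. The 7 lists had adjusted p = 0.89 to 0.92 with an estimated correlation. Without HA-Zbtb20 library 1, 0 of the 7 passed, and the microglia median turned to -0.15 and the Cajal-Retzius median became -0.26. Without 2KR library 4, 5 of them did not pass (microglia, GABA-A receptor, integrated stress response, unfolded protein and ribosomal protein). Without HA-Zbtb20 3, 5 or 6 or 2KR 3, 5 or 6, between 1 and 3 did not. The SUMO pathway list had a median of 0.01, a mean of -0.01 and 0 members past the test; median, mean and test differed in sign also for the isocortical, dentate, astrocyte, endothelial and fibroblast lists, none of which passed.

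The changes from KO with either virus were also set against each other. Of the genes called higher, 26 with HA-Zbtb20 and 110 with 2KR, 25 were shared, and of those called lower, 4 and 98, all 4 were shared. Independent lists would share 0.19 and 0.026, and groups simulated with no effect a median of 0. The comparisons use the same KO libraries, which adds to the overlap; with these split 3 and 3 the numbers shared had medians of 0 and 0, with 0.5 or fewer genes called as the median for either form and direction. Across genes, which are not independent replicates, the fold changes correlated at 0.71 with all KO libraries in both and at 0.43 in groups simulated with no effect. With the KO libraries split 3 and 3, the correlation had a median of 0.22 (-0.20 to 0.35 over 20 assignments) and the slope of 2KR on HA-Zbtb20 one of 0.22 (-0.32 to 0.38). The covariance was 0.0658 observed and 0.0424 simulated, a difference of 0.0234, and 0.03 with the libraries split. Simulated genes vary independently, unlike real ones, so chance can reach further than the simulated values show. The differences from those values are therefore not a test of likeness.

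Both virus groups were last compared with WT. Gna14 lay higher than in WT with HA-Zbtb20 (5.6 ± 0.41, adjusted p = 4.1e-07) and with 2KR (5.54 ± 0.41, adjusted p = 6.2e-07), as did Gli1 (3.99 ± 0.72 and 3.57 ± 0.74), the death-associated kinase gene Dapk2 (3.58 ± 1.01 and 3.51 ± 1.03) and the thrombospondin gene Thbs1 (2.84 ± 0.74 and 3.10 ± 0.77). Tfap2c (3.06 ± 0.30 and 2.75 ± 0.30) and the gap junction gene Gja5 (3.20 ± 0.84 and 3.56 ± 0.85) rose with both forms. Pdyn fell with HA-Zbtb20 (-2.84 ± 0.32, adjusted p = 6.5e-05) and with 2KR (-3.16 ± 0.35, adjusted p = 5.9e-05), as did Aqp4 (-3.11 ± 0.64 and -3.15 ± 0.70) and S100b (-3.27 ± 0.51 and -2.83 ± 0.53). Sox10 (-3.37 ± 0.77 and -2.52 ± 0.77), the adenylate kinase gene Ak7 (-2.84 ± 0.69 and -2.28 ± 0.69), Tbata (-2.46 ± 0.44 and -3.0 ± 0.48) and Ramp1 (-2.27 ± 0.56 and -2.75 ± 0.61), a subunit of the CGRP receptor, fell with both as well. All adjusted p of these genes were at or below 0.049 in edgeR, the value of Sox10 with 2KR, which no longer passed in 7 of 8 fits that left out 1 library. Dapk2 no longer passed in 7 of 9 such fits with HA-Zbtb20 and 7 of 8 with 2KR, and Thbs1 in 5 of 9 and 2 of 8. Of the 10 genes named for each group, 5 with HA-Zbtb20 and 4 with 2KR passed in every fit run. Without WT libraries 1 and 2, 1 astrocyte marker passed with HA-Zbtb20 and 0 with 2KR, so Aqp4 and S100b did not pass with 2KR. Of the oligodendrocyte lineage markers 0 passed with either form in that fit, so neither did Sox10. Of the 20 proliferation genes, 20 rose in each group, with medians of 1.45 and 1.40.

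In edgeR 1121 genes passed with HA-Zbtb20 against WT, 656 higher and 465 lower (966 without overlap; 3539 at an unadjusted p under 0.05), and 1370 with 2KR, 698 higher and 672 lower (1248 without overlap; 3899 at an unadjusted p under 0.05). Without WT libraries 4 and 5, 501 were higher and 617 lower with HA-Zbtb20, and 582 and 904 with 2KR. Without WT libraries 1 and 2, the numbers were 390 and 180, and 369 and 200. Over all tested genes 1790 (11.67%) and 2814 (18.35%) showed no overlap, where chance gives 1.59% and 2.86% on average over all groupings. Of the 200 genes higher in KO, 169 were also called higher with HA-Zbtb20 and 169 with 2KR, and of the 175 lower in KO, 130 and 134 were called lower. Independent lists would share 8.6, 9.1, 5.3 and 7.7, but these comparisons share the WT libraries, which adds to the overlap. Groups simulated with no change cannot show by how much, since a median of 0 genes was called in their KO. With the WT libraries split 2 and 2, so that none served both, a median of 55 genes rose in KO over 6 assignments. Of these a median of 34 was shared with HA-Zbtb20 and 34.5 with 2KR, where independent lists would share 0.812 and 0.759. A median of 61.5 fell in KO, with 32.5 and 35 shared, where independent lists would share 0.495 and 0.572. Without WT libraries 1 and 2, 570 genes passed with HA-Zbtb20 and 569 with 2KR, and of the 20 proliferation genes 18 and 16 did.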

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

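The tests of the astrocyte and the proliferation list in this part were chosen after the result was seen, while the one on shared variation between genes was chosen before. The 96 items searched were list scores as mean log2 CPM, CPM of named genes, total counts, genes detected and shares of counts. The shares were those of the most abundant, the mitochondrial and the ribosomal protein genes. Within groups of 4 to 6 libraries, Dixon's criterion sought a highest or lowest library far from the nearest other one. It picked 22 of 384 groups of values, where chance flags about 1 in 20, or 19. None of the 22 was a total, a number of genes detected or a share of counts.

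KO + HA-Zbtb20 library 1 had the highest score of the isocortical list, 5.72 (nearest 5.23), and of the neural progenitor list, 5.73 (nearest 4.97). Its GABA-A receptor score was the lowest, 6.4 (nearest 6.57). It also held the most Tfap2c, 26.7 CPM (nearest 18.2), Tox, 40.3 CPM (nearest 31.1), and Tpt1, 32.1 CPM (nearest 22.5). Library 2 of that group held the least Gna14, 7.97 CPM (nearest 9.76), and library 6 the most Hbq1b, 3.87 CPM (nearest 2.79), and Tbata, 0.967 CPM (nearest 0.486). WT library 1 had the highest scores of the integrated stress response list, 4.79 (nearest 4.36), and of the hypoxia and glycolysis list, 6.44 (nearest 5.48).

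KO library 3 had the highest CA1 score, 5.76 (nearest 5.36), the highest neurite score, 9.54 (nearest 9.37), and the most Aqp4, 128 CPM (nearest 68). KO library 4 held the most Gja5, 2.07 CPM (nearest 0.715), and KO library 6 the most Ccne2, 15.1 CPM (nearest 10.8). KO + 2KR library 3 had the highest choroid plexus score, 2.96 (nearest 1.99), and the most Mndal, 3.51 CPM (nearest 1.9). Library 5 of that group held the least Cox10, 18.9 CPM (nearest 22.6), and the most Gja5, 3.24 CPM (nearest 2.06). Library 6 held the most Ankrd13d, 48.2 CPM (nearest 38.3), and Selenow, 468 CPM (nearest 389).

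The astrocyte list stood lower in KO than in WT, with a median of -0.72 and an interquartile range from -0.98 to -0.43. A lower share of astrocytes as the whole cause stays open: 3 of the 14 markers moved apart from the mean of the others, Aqp4 by -2.06, S100b by -1.62 and Acsbg1 by 0.83 (exact permutation over 210 splits, adjusted p = 0.033, 0.044 and 0.033), but 0 rose past the test in edgeR, and under a lower share a marker that other cells express would fall less. With the fibroblast list as a covariate the median was -0.82, further from 0 than without it. Within groups, libraries with high fibroblast scores tended to have high astrocyte scores. A fit of this kind therefore cannot show a dilution of astrocytes by fibroblast-like cells, and more such cells in KO stay open. Without WT libraries 1 and 2 the median was 0.02, so those libraries as the whole cause stay open. They had the highest WT scores, so leaving them out had to shrink the shift. WT libraries 4 and 5 still scored 7.08 and 7.38 as mean log2 CPM, with the KO libraries between 6.23 and 7.84. Aqp4 and S100b, no longer past the test without WT libraries 1 and 2, stood at -2.27 and -1.83. An effect of the knockout on astrocytes was not tested and stays open; of the most abundant markers, Gfap stood at 1720 ± 800 CPM in WT and 999 ± 691 CPM in KO, Fabp7 at 1360 ± 420 and 941 ± 502 CPM, and 0 markers of the list belong to another list.

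The proliferation list stood higher with both HA-tagged forms than in KO, with medians of 0.57 and 0.53. A trend with GC content and transcript length was argued against as the whole cause, since the medians were 0.64 for HA-Zbtb20 and 0.58 for 2KR with the trend of other genes removed. The single members called over all genes fell from 1 and 3 to 0 and 0, for a cause not tested: genes at an unadjusted p under 0.05 went from 2280 to 1284 and from 2821 to 1259, and the log2 fold change of Bub1 from 1.02 ± 0.20 to 0.90 ± 0.21 with HA-Zbtb20 and from 1.12 ± 0.21 to 0.94 ± 0.22 with 2KR. With the fibroblast list as a covariate the medians were 0.61 and 0.55. That list hardly differed from KO (medians -0.11 and 0.06, median SE 0.89 and 0.94), so this fit could change little. No rise of fibroblast markers was seen, but at such SE more fibroblast-like cells are not excluded. With Xist as a covariate the medians were 0.56 and 0.52, and the members called also fell to 0 and 0. Unequal sexes were argued against as the whole cause for 2KR (1 female and 3 male, against 4 and 2 in KO). For HA-Zbtb20 (3 and 2) the shares were close, so that fit could change little. Chance in how the libraries were grouped was not tested for this list and stays open, and so does an effect of the virus or of Zbtb20 on dividing cells, which was not tested.

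Between the HA-tagged forms, fewer genes had an unadjusted p under 0.05 than chance gives for independent genes: 157 against 767 in the fit of all libraries and 179 against 734 in a fit of these libraries alone. In 7 of 100 splits of the 9 libraries, the real one among them, as few genes had such a p. The other splits had a median of 504 and reached 3302. That spread is consistent with variation shared by many genes within each group. No biological explanation was tested for this count.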

How the results depend on the processing

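The fits with the fibroblast list as a covariate, with the trend in GC content and length removed, and without WT libraries 1 and 2 or 4 and 5 were chosen after seeing the data, as was the choice to read likeness over all tested genes and to give called genes alone beside it (0.33, 0.03 to 0.63 over the 7 of 20 assignments with a value). Each count of genes was refitted under 12 other settings, or 14 against WT, 10 of them chosen before, and without each library of the compared groups (8 to 11 fits). For named genes, 3869 refitted values stayed on their side of the threshold and 1319 no longer passed; for lists 305 stayed and the others no longer passed. No gene changed sign and no list changed its camera direction, but the microglia median between the forms went from 0.15 to -0.15 without HA-Zbtb20 1 and to -0.06 without 2KR 4, and the astrocyte median in KO against WT to 0.02 without WT 1 and 2. The settings not mentioned below left each count within 1.5 times its main value.

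The 375 genes of KO against WT became 713 with DESeq2, 151 with only the compared groups, 214 with the Xist covariate, 628 with the fibroblast covariate and 225 without WT libraries 1 and 2 (135 of them among the 375). The 30 genes of HA-Zbtb20 against KO became 17 with total count scaling, 409 with DESeq2, 59 with limma voom, 5 with the Xist covariate and 115 with the fibroblast covariate, and in edgeR 0 with only the compared groups and with the GC and length trend removed (1909 and 1284 at an unadjusted p under 0.05). The 208 genes of 2KR against KO became 61 with no filter, 1090 with DESeq2, 445 with limma voom and 471 with the fibroblast covariate, and in edgeR 0 with only the compared groups, the Xist covariate and the trend removed (2459, 2430 and 1259 at an unadjusted p under 0.05). Against WT, the 1121 genes of HA-Zbtb20 became 570 without WT libraries 1 and 2. The 1370 of 2KR became 893 with no filter, 2140 with DESeq2, 902 with the trend removed and 569 without WT libraries 1 and 2. Between the forms the count was 0 in every setting. The fits of the compared groups alone have fewer libraries to estimate the spread; otherwise the cause was not tested.

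With the replicate block, the counts were 335 in KO against WT, 844 and 987 against WT, and in edgeR 0 for both forms against KO (2176 and 2837 genes at an unadjusted p under 0.05; DESeq2 and limma voom without the block gave 409 and 59, and 1090 and 445). Of 21 pairs of libraries with the same number, the median correlation was 0.08 (-0.46 to 0.56), 10 were over 0.1, and other pairs had a median of -0.03. The 3 pairs with number 3 stood at 0.17, 0.36 and 0.56, and 4 of 19 libraries correlated best with their own number. Not every pair was over 0.1 and no label says what a number stands for, so the numbers were not taken to pair the libraries. The 21 pairs include those of WT with knockout libraries. Among knockout libraries, numbers 1, 2 and 6 were female and 4 and 5 male in each group that had them. Number 3 was female in KO and male with both HA-tagged forms. Pairing within the knockout is thus not excluded. If present, the counts of 30 and 208 genes from fits without the block ignored it.

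Passing lists numbered 8, 7, 4 and 7 in the first 4 comparisons and 0 in each with an estimated correlation. With fry they were 6, 1, 0 and 0, and in KO against WT 15 without WT libraries 1 and 2. Likeness of the forms was 0.22, and 0.74 with all KO libraries in both fold changes, which then share error. It covers all tested genes, so it was not read at an adjusted p of 0.01. The cause of the other changes was not tested.

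Without each library in turn, counts ranged from 185 to 489 (KO against WT), 0 to 157 (HA-Zbtb20 against KO), 0 to 882 (2KR against KO), 0 to 0 (between forms), 693 to 1086 (HA-Zbtb20 against WT) and 740 to 1423 (2KR against WT). For lists these ranges were 7 to 16, 3 to 8, 3 to 6 and 0 to 13, for reversal -0.09 to 0.02 and -0.08 to 0, and for likeness 0.12 to 0.25. Counts that moved by more than 1.5 times were, in KO against WT, 208 without WT 1, 185 without WT 2, 244 without WT 4 and 249 without KO 6. In HA-Zbtb20 against KO they were 157 without KO 1, 0 without KO 2, 2 without KO 3, 9 without KO 4, 1 without KO 5, 96 without KO 6, and, for HA-Zbtb20 libraries, 0 without 1, 0 without 3, 5 without 5 and 55 without 6. In 2KR against KO they were 882 without KO 1, 91 without KO 2, 17 without KO 3, 22 without KO 4, 6 without KO 5, and, for 2KR libraries, 0 without 3, 2 without 4, 0 without 5 and 551 without 6. Against WT they were 693 without WT 1, 697 without WT 2 and 703 without HA-Zbtb20 5, and for 2KR 816 without WT 1, 795 without WT 2, 740 without 2KR 3, 797 without 2KR 4 and 779 without 2KR 5. For lists in KO against WT they were 16 without KO 1, 14 without KO 2 and 13 without KO 5, in HA-Zbtb20 against KO 3 without HA-Zbtb20 1, and between the forms 0 without HA-Zbtb20 1, 11 without HA-Zbtb20 2, 13 without 2KR 3 and 2 without 2KR 4.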

Other observations

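The counts of called genes in other splits were chosen before their results were seen, and those of genes at an unadjusted p under 0.05 after. For each comparison the libraries were split at random into groups of the same sizes and fitted on those libraries alone. In KO against WT, 4 of 100 splits, the real one among them, gave as many genes as the real 151, and 5 of 100 as many as the real 1717 at an unadjusted p under 0.05. The highest other count was 802, with WT libraries 1 and 2 and KO libraries 3, 4, 5 and 6 set against WT libraries 4 and 5 and KO libraries 1 and 2, and the second, 730, also parted WT libraries 1 and 2 from 4 and 5. The count of called genes thus lay just under the limit of 5 in 100 set before, and the other count reached it. With 100 of the 210 possible splits used, 4 in 100 cannot be told from that limit. Chance in the grouping therefore stays open, while a difference among the WT libraries was seen beside it.

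For HA-Zbtb20 against KO, the fit of these groups alone called 0 genes in edgeR (1909 at an unadjusted p under 0.05; DESeq2 called 409 and limma voom 59 in the fit of all libraries), and 100 of 100 splits gave as many, as every split must. The highest other count was 1497, with KO libraries 1, 2 and 5 on one side and 3, 4 and 6 on the other. For 2KR against KO, the fit of these groups alone also called 0 (2459 at an unadjusted p under 0.05; DESeq2 called 1090 and limma voom 445 in the fit of all libraries), 100 of 100 splits gave as many, and the highest other count was 1868, with the same parting of the KO libraries. Counts of 0 decide nothing on chance in the grouping. At an unadjusted p under 0.05, 11 of 100 splits gave as many genes for HA-Zbtb20 (highest other 3882, median 482) and 6 of 100 for 2KR (4037, median 460), so chance was not excluded by these counts. Between the forms, 0 genes were called (179 at an unadjusted p under 0.05; DESeq2 and limma voom called 0), 100 of 100 splits gave as many, and the highest other count was 887, with HA-Zbtb20 libraries 1, 2 and 3 and 2KR library 3 set against the rest; this count decides nothing either.

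Against WT, 1 of 100 splits, the real one, reached the 1066 genes of HA-Zbtb20, with 458 as the highest other count. For 2KR, 1 of 35 splits, the real one, reached the 1489 genes, and the highest other count was 0. Chance in the grouping was argued against for these comparisons.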
